A study of Caenorhabditis elegans with 2 samples.

How the data were processed

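The series holds ChIP-seq of whole Caenorhabditis elegans young adults (73 hours) of strain OP139, in which ceh-27 from a fosmid is fused to TY1, EGFP and FLAG tags, in an unc-119(ed3) background with an unc-119(+) marker. Chromatin was sheared by sonication to a size range of 200 to 800 and immunoprecipitated with anti-GFP, per the description in the labels, while their antibody field reads ceh-27. The sex is given as pooled male and female, without the share of each. The labels describe 2 biological replicates, numbered 4 and 1, which form a single group. A shared control is named beside the sample files and was not analysed here.

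Per the labels and the descriptions beside the sample files, the authors deposited 4 lists of regions on build ce11, namely 1 list for each replicate, 1 list from both replicates pooled, and the set that passed an irreproducible discovery rate (IDR) threshold. The aligner, the region caller and the IDR threshold are not given in the sources used here. The replicate and pooled lists each held exactly 30000 regions, so that they were capped and include background regions. For each region the authors deposited a signal value, whose scale is not stated, and a −log10 q value. The signal of the reproducible set is the authors' own value for each peak, equal to that of the pooled list, and was used only to describe and rank peaks within a list. The −log10 q values of the reproducible set ranged from 2.78 to 3.46 per the deposited file, with 1431 peaks at the ceiling, and were not used for ranking. The depth of the libraries is unknown because the lists hold no read counts, and no interval that needs depth was given. All p-values across peaks or genes measure peaks and genes, not animals, and 2 replicates of 1 group allow no test between groups.

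Regions were read with their summits as deposited and coordinates are given counted from 1. Sequence came from the WBcel235 assembly, the same assembly as ce11, and genes from Ensembl release 115. Every coordinate fell within the assembly's chromosome lengths, and mitochondrial DNA was left out. A promoter ran from 1000 bp upstream to 200 bp downstream of any annotated 5' end of a protein-coding transcript, and a gene was called bound when a reproducible summit fell in it. Annotated 5' ends in this worm are often trans-splice sites, and windows of neighbouring genes overlap. A summit was assigned to 5' untranslated, coding or 3' untranslated sequence in that order, then intron, then intergenic, and 2 summits in other exon sequence were left out of that comparison.

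Replicate overlap was tested with the 2328 strongest regions of each replicate, counting summits within 100 bp, against 1000 circular shifts of replicate 1 (one-sided). Promoter share and noncoding RNA classes (7 biotypes, summit within 200 bp of the gene) were tested against 1000 circular shifts, two-sided, where the smallest p is 0.0020, and features against 200 shifts. The 22 gene lists were tested with two-sided Fisher's exact tests over 19973 nuclear protein-coding genes. Benjamini-Hochberg adjustment was applied within each family (lists, biotypes, 6-mers) at 0.05. Of the list members, ram-4, elt-5 and opt-2 had no match by name in the annotation. Chromosome densities were compared with two-sided exact binomial tests and 95% exact intervals. Motifs and 6-mers were searched on either strand within 50 bp of the summit and compared with the window centred 300 bp to lower coordinates by exact McNemar tests. The trend over 4 equal groups by signal used 10000 permutations, and the bootstrap of rho 1000 draws. Windows matched for GC were drawn outside coding sequence and at least 200 bp from any pooled region, and all 2328 summits found a match with the same number of G and C bases. A further set of 2328 windows was drawn from the same sequence without regard to GC, to separate the change of background from the match.

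Tests, gene lists, thresholds and the AAGTG core were chosen before the data were examined, as was the rule for named items. That rule took the 20 peaks of highest signal with the gene whose 5' end is nearest, ceh-27 and unc-119, the 4 members with the strongest promoter peak in each list past the threshold and at most 2 in each other list, and the 5 most enriched and 3 most depleted 6-mers. Annotation features, distances, GC content, comparisons with noncoding windows, GC-matched or not, the 1164 strongest peaks, the set without peaks near tRNA genes, the splits by group of peaks, the gap around ceh-27, gene classes by symbol and the noncoding genes named were added after the data were seen. Alternatives covered the overlap rule, each replicate alone, promoter windows of 500 and 2000 bp upstream, shifts in place of Fisher's test, other windows, flanks and motifs, and distances of 500 bp and 50 kb. No pairing of samples applied, since there was 1 group.

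The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with a fixed seed of 7. The statistics were tested on simulated data. Of 600 shared summits planted in lists of 2328, 615 matches were found, against 15 in unrelated lists. For the gene lists, 82.0% of lists simulated at 4 times the odds were found and 0.501% of unchanged lists were called. No 6-mer of 2080 was called between unrelated windows, and a planted 6-mer ranked 1 by p. Equal pairs passed 0.05 in the motif test in 4.75% of draws, unrelated summits in the promoter test in 7.50%, and flat series in the trend test in 8.33%. For the chromosome comparison 95.0% of intervals held the simulated ratio of 1.4. The simulated genes were bound independently of each other, and the simulated windows all had the same base composition. In the data neighbouring promoters share peaks and summits are richer in GC than flanks, so these error rates may not hold for the real tests. The promoter and trend shares came from few draws.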

Results

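CEH-27 is a homeodomain protein of the NK-2 class in the nematode Caenorhabditis elegans. Its binding to chromatin was measured by ChIP-seq, in which DNA crosslinked to a protein is recovered with an antibody and sequenced. The worms were strain OP139, which carries a ceh-27 fosmid transgene fused to an EGFP tag, and an anti-GFP antibody was used on whole young adults at 73 hours. There was 1 group with 2 biological replicates, numbered 1 and 4, and no second condition. The design therefore gave 2 questions, namely how far the replicates marked the same regions and where in the genome the tagged protein was found. The peak lists held no read counts, so the depth of each library is unknown.

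The reproducible set held 2328 peaks with a median width of 344 bp, and together they covered 0.684% of the genome (build ce11). The highest signal, 1263, belonged to a peak on chromosome III from 10759099 to 10759434, in intergenic sequence with its summit 59 bp upstream of tasp-1. Next came the peaks upstream of the ribosomal protein genes rpl-3 (signal 1072; III, 3867440 to 3867720), rpl-15 (852; IV, 654792 to 655052) and rpl-35 (818; III, 7854563 to 7854825). Their summits were intergenic and lay 274, 352 and 452 bp upstream of the respective 5' ends. Also among the 20 strongest were peaks nearest to iff-2, a translation factor gene of the eIF5A kind (signal 694, 72 bp upstream), cdc-48.1, which encodes an AAA ATPase of protein turnover (667, 179 bp upstream), the cytochrome c oxidase subunit genes cox-5B (636, 16 bp upstream) and cox-5A (581, 289 bp upstream), and rps-1 (570, 255 bp upstream). The remaining peaks of the 20 were nearest to tag-340, W02H3.3, K12H4.5, ntl-2, F59C6.18, F55G7.5, ppfr-1, Y17G9B.5, F20B6.9, cest-16 and hsr-9, with signals from 573 to 729. Of these, W02H3.3 and F55G7.5 were 3963 and 1385 bp from an intergenic summit on X, and the summit nearest to cest-16 lay 3378 bp from it in an intron of mom-1. The ppfr-1 peak was also intronic, in ppfr-1 itself, 6595 bp downstream of its 5' end. Signal over the whole set ranged from 91.7 to 1263 with a median of 134.6.

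The replicates were compared first. The peaks at rpl-3 and tasp-1 were the 2 strongest in both, with rpl-3 first in replicate 1 and tasp-1 first in replicate 4, and rpl-15 ranked 3 and 7. Of the 2328 reproducible peaks, a set chosen from these same replicates, 1700 (73.0%) had a summit within 100 bp among the 2328 strongest regions of replicate 1 and 1932 (83.0%) among those of replicate 4. Among the 2328 strongest regions of each replicate, 1392 (59.8%) were shared, against a mean of 11.3 and a maximum of 27 after circular shifts of replicate 1 along the chromosomes. The one-sided permutation p was 0.000999, the smallest that 1000 shifts can give. Agreement was closer at the top, with 782 of the 1164 strongest regions shared (67.2%). Over the 2186 reproducible peaks matched in both lists, the signals of the replicates had a Spearman's rho of 0.566 (95% bootstrap interval 0.529 to 0.595) and a Pearson's r of 0.641 on the log2 scale. These correlations run across peaks, which are not independent replicates, and under a 50% reciprocal overlap of the intervals rho was 0.469. The reproducible set coincided with the 2328 strongest regions of the pooled list (2328 of 2328), so its lower edge was set by pooled signal.

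**Figure D1:**
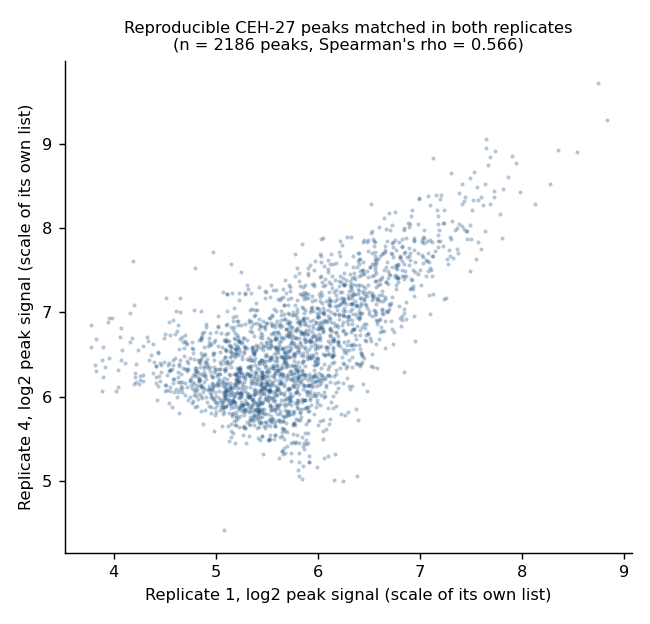
Each point is 1 of the 2186 reproducible peaks matched in both replicates, with the log2 signal of replicate 1 on the x axis and of replicate 4 on the y axis, each on the scale of its own list. Spearman's rho was 0.566, and the points spread most at the lower end.

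Promoters of protein-coding genes, where transcription starts, held far more summits than shifted positions gave. In all, 1317 of the 2328 summits (56.6%) lay between 1000 bp upstream and 200 bp downstream of an annotated 5' end, against 25.7% after circular shifts (95% of shifts from 23.9% to 27.6%), a 2.20-fold difference. The two-sided permutation p was 0.0020, the smallest that 1000 shifts can give. Promoter summits sat a median of 212 bp from the nearest 5' end, and 90.8% of them were on its upstream side. The window itself lies mostly upstream, so a large upstream share follows from its definition. Of all summits 74.3% were upstream of the nearest 5' end, and of those outside promoters 52.7%. By annotation, 1569 summits (67.4%) were intergenic against 37.1% by shift, and 94 (4.04%) were in 5' untranslated sequence against 1.77%. Coding sequence held 62 summits (2.66% against 24.1%), introns 584 (25.1% against 33.5%) and 3' untranslated sequence 17 (0.730% against 3.35%). Each of these 5 differences had a permutation p of 0.00995, the smallest that 200 shifts can give. In 4 groups of 582 peaks ordered by signal, the share in promoters rose from 49.7% in the weakest group through 53.4% and 58.4% to 64.8% in the strongest. The permutation p of that trend was 0.0001, the smallest that 10000 permutations can give. Promoters of ribosomal protein genes rose from 1.20% to 4.47% of peaks over the same groups (permutation p = 0.0004).

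A promoter peak was found at 1691 of 19973 protein-coding genes (8.47%). Of the 22 gene lists, 8 were bound more often than other genes, and all 8 hold broadly used or neuronal genes. Ribosomal protein genes stood furthest out, with 57 of 80 bound (71.3%) against 8.21% of other genes. By two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 22 lists, their odds ratio was 27.7 (95% interval 16.7 to 47.2; adjusted exact p = 6.86e-42). The respiratory chain and ATP synthase list followed with 20 of 44 genes (odds ratio 9.11, adjusted exact p = 5.70e-10), among them cox-5B, cox-5A, the ATP synthase gene atp-1 (signal 374, 4 bp upstream) and cox-6B (305, 151 bp upstream). In the spliceosome list 13 of 35 genes were bound (odds ratio 6.43, adjusted exact p = 8.61e-06). Its strongest peaks were at prp-19 (signal 548, 630 bp upstream) and prp-8 (284, 307 bp upstream), and the neighbours rsp-1 and rsp-2, both SR splicing factor genes, shared a peak of signal 237.

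Genes of protein folding, the proteasome, translation and acidification were also bound more often. Of the heat shock and chaperonin list 20 of 59 genes had a promoter peak (odds ratio 5.60, adjusted exact p = 1.57e-07), including the chaperone genes hsp-90 (signal 440, 389 bp upstream), hsp-3 (440, 25 bp upstream), hsp-60 (432, 614 bp upstream) and the chaperonin subunit gene cct-7 (384, 296 bp upstream). The proteasome list had 11 of 33 (odds ratio 5.43, adjusted exact p = 1.14e-04), led by rpn-3 (signal 275) with rpn-11 (164), rpn-9 (141) and pas-1 (121) below it, and its odds ratio was 3.07 in replicate 4 alone and 1.94 among the 1164 strongest peaks, where it was no longer called (adjusted exact p = 0.321). Translation factors had 13 of 40 (odds ratio 5.24, adjusted exact p = 4.11e-05), among them iff-2, the elongation factor gene eef-1A.1 (signal 373) and the initiation factor genes eif-3.C (358) and eif-3.B (309). Among vacuolar ATPase genes, which encode the proton pump of acidic compartments, 7 of 21 were bound (odds ratio 5.42, adjusted exact p = 2.27e-03), with vha-8 (signal 288), vha-12 (272), vha-13 (251) and vha-1 (245) strongest. The pan-neuronal list had 13 of 43 (odds ratio 4.71, adjusted exact p = 8.73e-05), and in replicate 1 alone 8 of 43 (2.48, adjusted exact p = 0.0441). Its 4 strongest members were unc-16 (signal 255) and unc-14 (247), both linked to axonal transport, the tubulin gene tbb-1 (174) and unc-76 (173). Among the ribosomal protein genes the 4 strongest were rpl-3, rpl-15, rpl-35 and rpl-20 (signal 593), the last sharing its peak with Y17G9B.5.

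Bound less often than other genes were 5 lists, all of them large gene families. Of the serpentine chemoreceptors, 8 of 1309 genes had a promoter peak (0.611% against 9.02%; odds ratio 0.0620, adjusted exact p = 2.91e-39), with sre-23 (signal 269), sri-5 (202), srh-89 (164) and sre-1 (144) strongest. The C-type lectin list had 1 of 240, clec-126 (odds ratio 0.0447, adjusted exact p = 1.56e-07; 0.191 in replicate 4 alone). The F-box list had 5 of 322 (odds ratio 0.168, adjusted exact p = 5.63e-07), with fbxb-85 (signal 234.9), fbxa-90 (215), fbxa-83 (186) and fbxa-24 (140) strongest. The only neuropeptide gene of 145 was ins-39 (signal 478; odds ratio 0.0745, adjusted exact p = 1.33e-04; 0.227 in replicate 1 alone and 0.158 in replicate 4 alone), and the cuticle collagens had 4 of 174, namely col-38 (signal 225), col-71 (181), col-185 (170) and col-2 (126; odds ratio 0.253, adjusted exact p = 2.40e-03). The collagens' odds ratio was 0.404 in replicate 4 alone and 0.338 among the 1164 strongest peaks, where they were no longer called (adjusted exact p = 0.0904). Against circular shifts of the summits, only the chemoreceptors of these 5 lists stayed called (0.266-fold of the shifted count, adjusted permutation p = 0.00488, from the smallest p that 1000 shifts can give). The others were at 0.164-fold for the lectins (adjusted permutation p = 0.0816), 0.225-fold for neuropeptides (0.173), 0.553-fold for F-box genes (0.415) and 0.827-fold for collagens (1), with shifted means of 6.10 genes for the lectins and 4.45 for neuropeptides. All 8 lists bound more often were also called against the shifts, at 6.08-fold to 24.3-fold, while all protein-coding genes together were bound 2.65-fold more often than by shift.

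The remaining 9 lists did not pass the test. Homeobox genes had 5 of 100 bound (odds ratio 0.568, adjusted exact p = 0.360), with an odds ratio of 0.333 in replicate 1 alone. The NK-2 gene ceh-22 (signal 224), also in the pharyngeal list, and ceh-38 (222) were strongest. Nuclear hormone receptors had 18 of 274 (0.758, 0.396), led by nhr-47 (signal 246) and nhr-48 (210), and against shifts their count was 2.24-fold (adjusted permutation p = 0.00879), below the 2.65-fold of all genes. Body wall muscle genes had 6 of 42 (1.80, 0.242), led by cpn-3 (signal 243) and act-4 (170), and were at 3.30-fold against shifts (adjusted permutation p = 0.0320). Germline genes had 6 of 64 (1.12, 0.820), with cgh-1 (signal 191) and nos-3 (123) strongest and an odds ratio of 0.531 in replicate 1 alone, and histones 7 of 72 (1.16, 0.737), with his-37 (signal 510) and his-24 (201). Pharyngeal genes had 1 of 28 (ceh-22, 0.400, 0.591), epidermal and seam cell genes 1 of 27 (ajm-1, signal 166, 0.415, 0.759) and intestinal genes 1 of 46 (fat-6, signal 118, 0.240, 0.247). The odds ratio of the epidermal and seam cell list was 0.865 in replicate 1 alone and 0.910 in replicate 4 alone. None of the 31 major sperm protein genes was bound (adjusted exact p = 0.168). Of the promoter peaks, 406 (30.8%) lay in the windows of at least 2 genes, so that a bound gene is not always the only candidate.

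**Figure D2:**
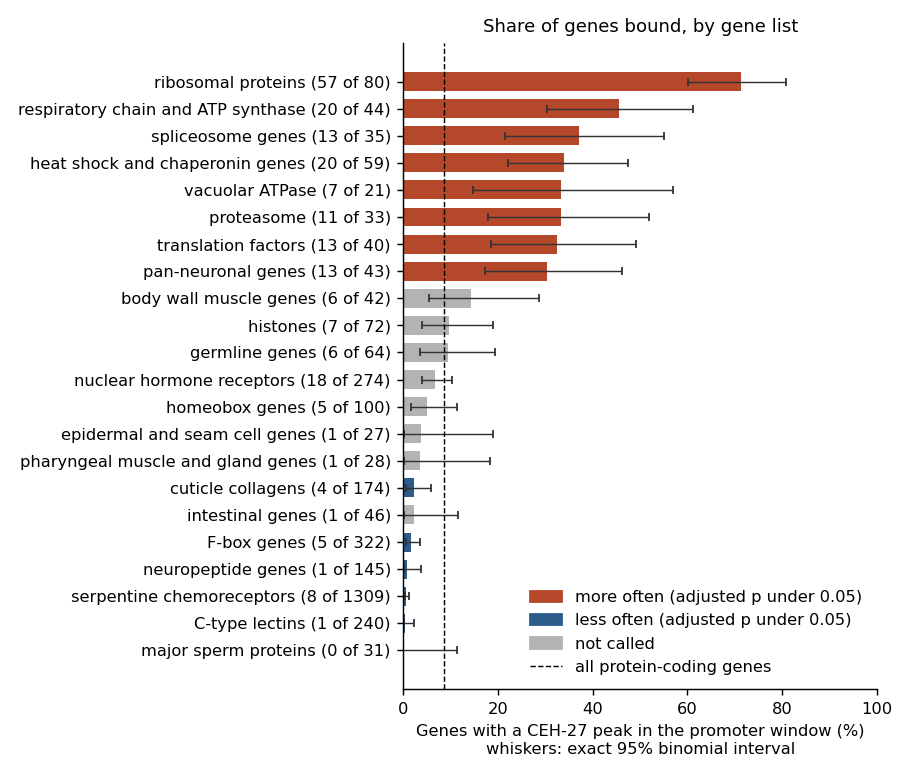
Bars show the percent of genes in each of the 22 lists with a reproducible peak in the promoter window, with exact 95% binomial intervals, and the dashed line marks the 8.47% of all protein-coding genes. Ribosomal protein genes reached 71.3%, and 8 lists are coloured as bound more often and 5 as bound less often.

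Noncoding RNA genes carried many of the peaks outside promoters. A summit lay within 200 bp of 238 of 612 tRNA genes (38.9%), 32.2-fold more than the mean of 7.38 after circular shifts. Of 346 snoRNA genes, which guide the modification of other RNAs, 79 had a summit (18.4-fold), as did 20 of 129 snRNA genes (13.9-fold). The folds depended on the distance allowed, with 15.2, 10.8 and 6.95 for tRNA, snoRNA and snRNA genes within 500 bp and 107, 12.1 and 21.3 with the summit inside the gene. At 200 bp all 3 had an adjusted permutation p of 0.00350, from the smallest p that 1000 shifts can give. Whether the signal at these genes depends on CEH-27 was not tested. At tRNA genes the summits lay a median of 10 bp downstream of the gene's 5' end (quartiles 18 bp upstream to 42.8 bp downstream), while at snoRNA genes the median lay 38 bp upstream. The strongest peaks of these classes, named after their values were seen, were at sls-2.4 (signal 556; chromosome I, 4172017 to 4172462), sls-2.1 (510; II, 5844639 to 5844902) and sls-2.2 (451; II, 5543435 to 5543667), genes of the SL2 trans-spliced leader RNA, and at the snoRNA genes F59C6.15 (674), ZK994.7 (545) and C51F7.4 (512). The strongest tRNA gene peak had a signal of 389 and lay on chromosome IV from 15931285 to 15931470, in an intron. MicroRNA genes (9 of 261, 2.92-fold, adjusted permutation p = 0.0303) and lincRNA genes (15 of 194 against a mean of 7.14, adjusted permutation p = 0.0280) passed the test in the reproducible set. Neither passed among the strongest regions of replicate 1 alone (adjusted permutation p = 0.133 and 0.0951). All protein-coding genes together were bound 2.65-fold more often than by shift, although in a different window. The lincRNA fold lay below that value and the miRNA fold close to it. Passing this test therefore does not set miRNA or lincRNA genes apart from genes in general. The piRNA genes were under-represented, with 17 of 15363 against a mean of 129.7 (0.131-fold, adjusted permutation p = 0.00350), and none of 20 rRNA genes had a summit (mean 0.349 by shift).

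**Figure D3:**
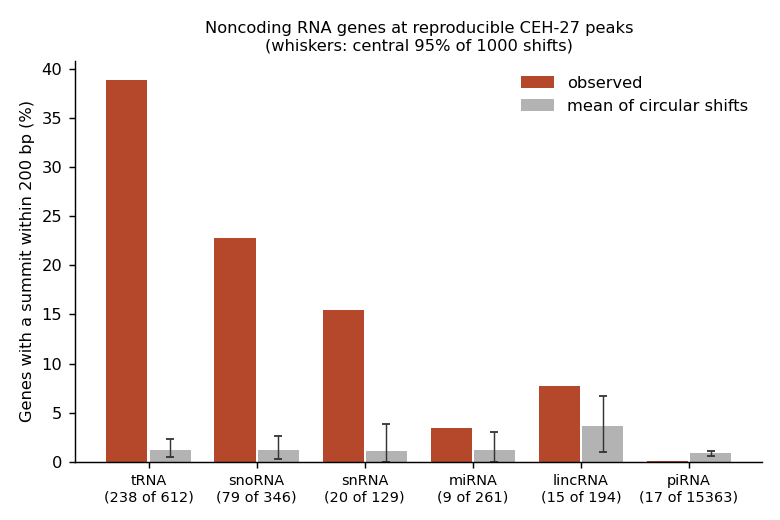
For each class of noncoding RNA gene, paired bars give the percent of genes with a reproducible summit within 200 bp and the mean percent after 1000 circular shifts, with whiskers for the central 95% of shifts. The tRNA genes reached 38.9%, and piRNA genes lay below their shifted value; rRNA genes, with none, are left out.

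Peaks were densest on the X chromosome of these worms, whose sex the labels give as pooled male and female, with 29.6 per Mb against 27.8 on III, 24.7 on I, 23.04 on II, 19.8 on IV and 16.6 on V. The ratio of X to the autosomes was 1.36 (95% interval 1.23 to 1.496, two-sided exact binomial p = 2.13e-09), with 1.21 among the strongest regions of replicate 1 alone and 1.42 in replicate 4 alone. That test pools the autosomes and counts peaks as independent, so its p and interval leave out the spread between chromosomes. Chromosome III was close to X in density, and outside promoters the autosomes ran from 6.36 per Mb on V to 12.1 on III, against 15.7 on X. Promoter peaks per Mb did not show the X excess (ratio 1.07, 0.928 to 1.23, exact p = 0.348), whereas peaks elsewhere were 1.78-fold denser on X (1.54 to 2.04, p = 5.93e-15). Accordingly 46.9% of the 525 X peaks lay in promoters against 59.4% of autosomal peaks (Fisher's exact p = 4.12e-07). Per protein-coding gene, the X to autosome ratio over all peaks was 1.84 (1.66 to 2.03). X held 246 promoter peaks for 2731 protein-coding genes, the most per gene of any chromosome. The autosomes held 228 for 2878 on I, 206 for 3449 on II, 216 for 2640 on III, 206 for 3281 on IV and 215 for 4994 on V. The ratio of promoter peaks per gene was not tested. The X chromosome holds 276 of the 612 tRNA genes (45.1%), and 79 of its 279 peaks outside promoters lay within 200 bp of a tRNA gene. Without peaks near tRNA genes, the X to autosome ratio was 1.18 over all peaks (1.05 to 1.31, exact p = 3.28e-03) and 1.44 outside promoters (1.22 to 1.69, p = 1.19e-05). With each autosome split into 3 equal parts, the middle part was 1.58-fold denser in peaks than the outer parts (1.44 to 1.74, exact p = 1.52e-21), and per protein-coding gene the ratio was 1.28 (1.17 to 1.41).

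**Figure D4:**
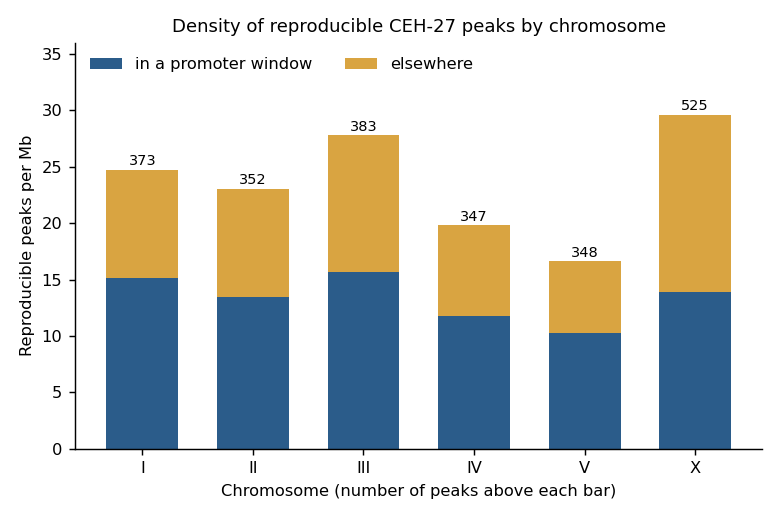
Stacked bars give reproducible peaks per Mb on each chromosome, split into summits in a promoter window and elsewhere, with the number of peaks above each bar. The X chromosome has the tallest bar, 29.6 per Mb, and 15.7 per Mb of it lies outside promoters.

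The sequence AAGTG, the core that NK-2 class homeodomains are known to bind, was more frequent at summits than beside them. It occurred within 50 bp of 27.1% of summits and in 20.9% of equal windows centred 300 bp away at lower coordinates. The odds ratio of discordant peaks was 1.42 (95% interval 1.23 to 1.63; two-sided exact McNemar p = 7.67e-07). Many other sequences also differed from the flank, with 788 of 2080 6-mers more frequent at summits. This test by itself therefore does not set AAGTG apart from other sequences. With a pyrimidine before the core (YAAGTG) the shares were 11.9% and 6.01% (odds ratio 2.05, 1.66 to 2.56, exact p = 6.45e-12), whereas the general homeodomain core TAATT went the other way, with 12.8% against 39.6% (odds ratio 0.229, 0.194 to 0.269, p = 3.71e-93). Summit windows had a mean GC content of 49.4% ± 7.16 (SD over 2328 windows) against 35.1% ± 8.48 in the flank. Compared with noncoding windows of the same GC content, the odds ratios were 1.51 for AAGTG (1.31 to 1.74), 2.04 for YAAGTG (1.64 to 2.55) and 0.770 for TAATT (0.643 to 0.921). Against noncoding windows drawn without regard to GC they were 1.55, 2.36 and 0.217. By group of peaks, AAGTG had an odds ratio of 1.57 in promoters outside the 8 lists bound more often (1.28 to 1.92), 1.12 in the promoters of those lists (0.634 to 1.97) and 0.725 near tRNA genes (0.433 to 1.20). The share of peaks with AAGTG did not rise with signal, from 27.7% of the 582 weakest to 27.5% of the 582 strongest (permutation p for trend 0.593).

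**Figure D5:**
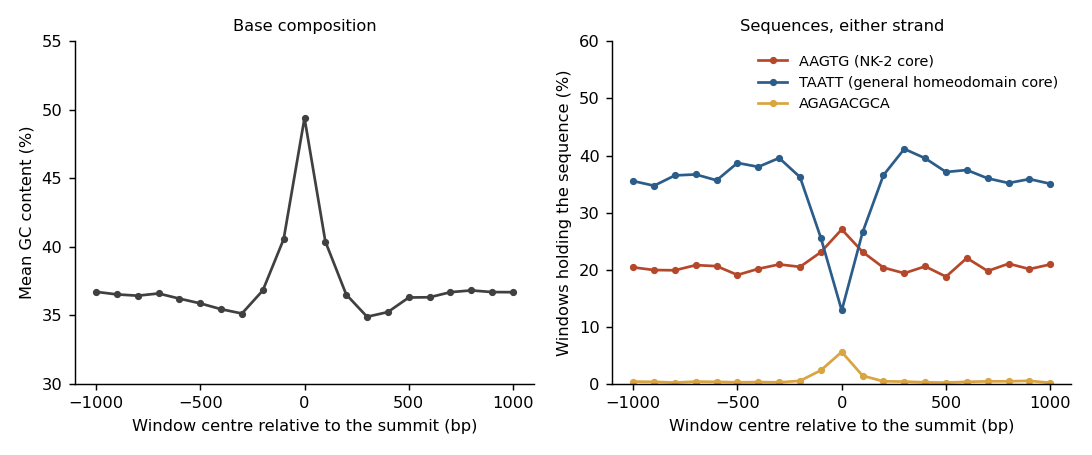
Left, mean GC content of windows of 50 bp to each side at 100 bp steps from the summits of the 2328 reproducible peaks; right, the percent of those windows holding AAGTG, TAATT or AGAGACGCA on either strand. GC content rose to 49.4% at the summit, AAGTG to 27.1% and AGAGACGCA, joined from 6-mers after they were seen, to 5.58%, and TAATT dropped to 12.8%.

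GC-rich 6-mers led the summits. Of 2080 strand-collapsed 6-mers, 788 were more and 545 less frequent in the summit windows than in the flank (exact McNemar tests, Benjamini-Hochberg adjusted p under 0.05). The most enriched were CGGCCG (4.64% of summits against 0.430%, odds ratio 13.3, adjusted exact p = 8.04e-22), GCGCGC (8.29% against 0.644%, 12.9), CGCGCG (5.93% against 0.473%, 12.5), ACGCGC (11.6% against 1.20%, 11.1) and AGACGC (15.2% against 1.72%, 10.2, adjusted exact p = 3.27e-64). The most depleted were TAATAA (2.06% against 12.2%, odds ratio 0.139), TATTAA (1.46% against 9.11%, 0.156) and ATAATA (2.06% against 11.2%, 0.158). Against noncoding windows drawn without regard to GC 936 6-mers were more frequent and 542 less, and against those of the same GC content 388 and 402. In the latter the odds ratio of AGACGC was 3.31 (adjusted exact p = 1.46e-27) while that of CGCGCG was 1.42 (adjusted exact p = 0.0386). Repeats of GA and CA, named after their values were seen, were also higher than in windows of the same GC content. Their odds ratios were 3.71 for GAGAGA (adjusted exact p = 2.99e-54), 3.34 for AGAGAG (8.27e-42) and 3.35 for ACACAC (8.28e-30). None of the 3 depleted 6-mers was called against those windows, where their adjusted p-values were 0.0564 for TAATAA, 0.678 for TATTAA and 0.102 for ATAATA.

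The loci of the transgene were examined separately, since the strain carries extra copies of ceh-27 and of its marker unc-119. No reproducible peak lay within 20 kb of ceh-27 (WBGene00000449; V, 11661549 to 11665102, minus strand) or of unc-119 (WBGene00006843; III, 10902641 to 10908935, plus strand), where other windows of the same size held a median of 1. Around ceh-27 the pooled list and both replicate lists also held no region within 20 kb, against a median of 13 regions in other windows. Whether sequence here was masked before the lists were made is not given in the sources used here. The empty stretch in the pooled list ran for 62.4 kb, from a summit at 11638778 to one at 11701140, which put it among the 43 longest of the 29994 gaps between neighbouring summits. In replicate 1 it was 66.6 kb, among the 3 longest gaps, and in replicate 4 it was 62.4 kb, among the 45 longest. The unc-119 locus had 14 pooled regions within 20 kb against a median of 14, the strongest with a signal of 59.6.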

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

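The 1164 strongest peaks, the noncoding windows, GC-matched or not, and the set without peaks near tRNA genes were chosen after the data were seen. Using either replicate alone left the promoter share (54.2% to 56.3%), the X ratio (1.21 to 1.42), the AAGTG odds ratio (1.44 to 1.45) and the counts of lists called on the same side of their thresholds. Among the comparison-level results, 3 values moved and 1 reversed, and the other 69 alternatives that could differ stayed the same, which for counts means within 1.5 times and not that each call was kept. Noncoding classes called fell from 6 to 4 without replicate 4 (miRNA and lincRNA) and with summits inside the gene, the fold of tRNA genes ran from 15.2 within 500 bp to 107 inside the gene, and lists bound more often rose from 8 to 10 under circular shifts. Leaving out 1 replicate moved the odds ratio of pan-neuronal genes from 4.71 to 2.48, proteasome from 5.43 to 3.07, translation factors from 5.24 to 8.06, C-type lectins from 0.0447 to 0.191, neuropeptides from 0.0745 to 0.227 and collagens from 0.253 to 0.404, all still called. Among uncalled lists it moved germline genes from 1.12 to 0.531, histones from 1.16 to 0.806 and homeobox genes from 0.568 to 0.333. Epidermal and seam cell genes moved from 0.415 to 0.910 and pharyngeal genes from 0.400 to 0. The cause was not tested. Under a 50% reciprocal overlap rho was 0.469, and the cause was not tested. Under circular shifts 1 list, the chemoreceptors, was called as bound less often in place of 5, although lectins (0.164-fold) and neuropeptides (0.225-fold) lay as low as the chemoreceptors (0.266-fold), and the nuclear hormone receptors changed sides, at 2.24-fold. Shifted summits bind a mean of only 638.6 genes against 1691 (2.65-fold), so that this comparison sets a lower baseline for every list by construction, and 2.24-fold is no enrichment over other genes. With TAATT in place of AAGTG the odds ratio was 0.229, with 0.217 against noncoding windows of any GC and 0.770 against those of the same GC, so that GC content goes with most of the depletion. Against noncoding windows of the same GC 388 6-mers were higher in place of 788, and against those of any GC 936, so that the fall came with the match and not with the change of background. Among single lists and biotypes, 153 of the alternatives kept the call, where an uncalled item counts as kept while it stays uncalled. Among the 1164 strongest peaks proteasome genes (odds ratio 1.94, adjusted exact p = 0.321), collagens (0.338, 0.0904) and miRNA genes (2.63-fold, adjusted permutation p = 0.2005) were no longer called, and with promoters of 2000 bp upstream nuclear hormone receptors were bound less often (0.587, 0.0324). The planned IDR of 0.01 was not run because the lists hold no IDR value per peak. The strongest pooled regions and the pooled score gave the same set and order, and leaving out peaks near ceh-27 and unc-119 removed none, so these say nothing about stability and are not in the counts. No paired analysis was possible because there was a single group. Depth is unknown, so what it limits was not estimated.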

Other observations

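The gene classes, the joined sequence, and the tests of the intestinal list, of weaker regions on X, and of X without the motif or without tRNA genes were chosen only after the result was seen. No biological explanation by group was tested, since the design has 1 group.

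Gene classes defined by their symbol, an exploratory family of 172 classes with at least 10 members, gave 15 classes bound more often and 12 less often (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). Besides the classes within the lists above, genes named lin for abnormal cell lineage had 18 of 47 bound (odds ratio 6.77, adjusted exact p = 1.10e-06). Also bound more often were 11 of 31 vps genes of vacuolar protein sorting (odds ratio 5.98, adjusted exact p = 7.65e-04) and 7 of 20 rab genes of small GTPases (5.84, 0.0114). The sec (4 of 14, odds ratio 4.33, adjusted exact p = 0.123) and tbc genes (3 of 17, 2.32, 0.463) were not called. Genes named unc (18 of 94, 2.58, 0.0114), madf (4 of 10, 7.22, 0.0469) and tag (11 of 57, 2.60, 0.0481) were called. Higher as well were 8 of 26 nuclear pore genes named npp (4.82, 0.0114), 5 of 13 algn genes of protein glycosylation (6.77, 0.0298) and 9 of 41 mitochondrial ribosome genes named mrpl (3.05, 0.0439), while the mrps genes of the same ribosome had 3 of 28 (1.30, 0.935). None of the 67 ugt genes, which encode glucuronosyltransferases, was bound (adjusted exact p = 0.0439).

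The 6-mers AGAGAC, AGACGC and GACGCA overlap and spell AGAGACGCA, a sequence assembled after they were seen. It occurred in 130 of 2328 summit windows (5.58%), against 0.258% of flanks and 1.37% of GC-matched noncoding windows. Because its parts were chosen for their enrichment at these same summits, a test of the difference on them carries no weight and none is given. It was found at 6.00% of promoter summits outside the lists bound more often, at 6 of the 150 in their promoters (4.00%), at 5.34% of summits outside promoters, at 1 of the 54 in ribosomal protein promoters (1.85%) and at 1 of 218 summits near tRNA genes (0.459%).

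The bound genes were rich in ribosomal protein and other broadly used promoters. Sequence-specific binding through AAGTG is a hypothesis that stays open there, because the odds ratio at the 150 peaks in promoters of the enriched lists was 1.12 with an interval from 0.634 to 1.97. The longer YAAGTG had an odds ratio of 2.56 (1.14 to 6.28) at the same peaks, an alternative with few discordant peaks (23 against 9). A signal that rises at any strongly used adult promoter was not seen in the intestinal list, which holds the vitellogenin genes. Its odds ratio was 0.240 with an upper limit of 1.41, below the lowest lower limit of the enriched lists, 1.85. The list covers 46 genes of a single tissue and no expression values were used, so it cannot decide about strongly used promoters in general. Recovery of broadly open promoters, or of tRNA, snoRNA and snRNA genes, regardless of the factor was not tested, since ChIP of other factors was not used here.

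The X excess, measured without the spread between chromosomes, may have several sources. An offset between ChIP and control along all of X was not seen in the pooled regions below the reproducible set, which were 0.942-fold as dense on X as on autosomes (0.913 to 0.972). These regions are what was left after the strongest were taken from a capped list, so they cannot decide about an offset. Promoter peaks alone are not the seat of the excess per Mb, since peaks elsewhere had a ratio of 1.78. Per protein-coding gene, X held the most promoter peaks of any chromosome, a difference that was not tested. The sequence TCGCGCAGGGAG, known from recruitment sites of the X dosage compensation complex, was found within 2 mismatches at 13 of 279 X peaks outside promoters and at 6 of 732 autosomal ones (odds ratio 5.91, 2.07 to 19.1, Fisher's exact p = 2.17e-04). It was also found at 7 of 246 X promoter peaks (2.85%), where the density per Mb showed no excess. Flanks of the X peaks outside promoters held it at 2 of 279, and GC-matched noncoding windows at 25 of 2328 (1.07%). The higher share on X goes with the hypothesis that such sites give part of the excess. It cannot decide this, because no GC-matched windows from X alone were compared. Without the peaks that hold the sequence, the ratio outside promoters was 1.71 (1.48 to 1.97). So few peaks could change it only a little, and recruitment sites without the sequence within 50 bp of the summit stay in. That removal therefore cannot decide whether such sites are the whole source. Leaving out peaks near tRNA genes lowered the ratio outside promoters from 1.78 to 1.44 (1.22 to 1.69). These peaks therefore carry part of the pooled ratio. The interval leaves out the spread between chromosomes, and with all peaks kept III had 12.1 per Mb outside promoters against 15.7 on X. Single chromosomes were not compared without these peaks, so whether X still exceeds each autosome was not settled. With the peaks that hold the sequence and those near tRNA genes both left out, the pooled ratio was 1.36 (1.15 to 1.60), and what remains is open.

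GC-rich 6-mers led the summits, and base composition could have produced them. Of the 788 6-mers higher than in the flank, 292 (37.1%) were also higher against noncoding windows of the same GC content and 46 were lower, which argues against GC content as the whole cause while leaving it open for the others. For the NK-2 core the odds ratio against those windows was 1.51 (1.31 to 1.74), so GC content does not account for it. With 388 of 2080 6-mers also higher there, that ratio by itself does not set AAGTG apart from other sequences.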
